A study of Mus musculus with 2 samples.

How the data were processed

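Chromatin immunoprecipitation followed by sequencing was used to map trimethylation of lysine 27 on histone H3 (H3K27me3), the mark that Polycomb repressive complex 2 places on silenced developmental genes, in hindbrain from mouse embryos at embryonic day 11.5. Per the labels, the series holds a single group of 2 biological replicates. Replicate 1 was a pool of 109 embryos and replicate 2 a pool of 88 embryos, each mixing males and females and each carrying 2 technical replicates. The pools are separate biological samples, so a spread over the replicates includes variation between pools, but with n = 2 it is poorly estimated.

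The authors deposited 4 lists of narrow peaks on the mm10 (GRCm38) assembly. Per the descriptions deposited with the lists, peaks were called on the filtered alignments of each biological replicate separately and on the alignments of both replicates together (the pooled list). Per the same descriptions deposited with the lists, the replicated peaks were derived from these 3 lists. The rule by which a peak counted as replicated, the aligner, the peak caller, its version and its threshold were not given in the sources used here. Each deposited peak carries start, end and summit coordinates in bp, a display score, an enrichment score, and a −log10 p and a −log10 q value, all of them the authors' own values for that peak. The reference against which the deposited enrichment score was formed was not given in the sources used here, so this score served only to rank, filter or describe peaks within a list. Numbers of reads were not given in the sources used here. The sequencing depth behind each list is therefore unknown, and no interval that needs it is reported. A peak list shows where enrichment passed a threshold, so a gene without a peak may still carry a lower level of the mark. The lists also held weak peaks. The lowest −log10 p was 2.05 in the replicated list, 2.02 in the pooled list, 2.03 in replicate 1 and 2.06 in replicate 2. A q above 0.05 was carried by 15.3% of replicated, 29.4% of pooled, 26.6% of replicate 1 and 16.3% of replicate 2 peaks. A peak at a gene may therefore rest on weak evidence.

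Peaks on chromosomes 1 to 19 and X were analysed, which left out 1 peak of replicate 1 and 3 peaks of replicate 2 on other sequences. Genes were the 21728 protein-coding genes of GENCODE mouse release M21 on these chromosomes. The transcription start site (TSS) was the 5′ end of the gene record, and a promoter was TSS ±1 kb. A promoter counted as marked when a peak overlapped it by at least 1 bp. Coverage of a gene was the percent of base pairs in TSS ±5 kb that lay in peaks. Peaks closer than 3 kb were stitched into domains. The genomic distribution assigned each covered base pair to promoter, exon, intron or intergenic sequence in that order. Coordinates are printed as a genome browser counts them, from 1.

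Before the data were examined, 19 gene lists with 329 entries were fixed, of which 326 matched protein-coding genes. The imprinted transcripts H19, Kcnq1ot1 and Meg3 are noncoding and were not analysed here. The share of marked promoters in each list was compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 19 lists, at a threshold of 0.05. Mean coverage of gene lists was compared by two-sided permutation tests with 100000 resamples. Neighbouring genes share domains, so genes are not independent units in these tests. The overlap of the replicates was compared one-sided with 100 circular shifts of the peaks of replicate 2 within each chromosome, for which the smallest possible p is 0.0099. Chromosome X was ranked among the chromosomes without a test. Series-level results rest on the replicated list, and each replicate's own list was analysed beside it.

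Genes were named by a rule set in advance. Named were the protein-coding genes overlapping the 15 longest domains, the 2 best and the 2 least covered members of each gene list, the 10 genes whose promoter held the replicated peak of highest enrichment, and the 5 genes per replicate with the strongest promoter peak found in that replicate only, of which the first 3 are printed. Other members of the fixed lists were named with their values where useful.

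Alternatives covered each replicate's list alone, the pooled list, a −log10 p of at least 5, the 50% of replicated peaks with the higher enrichment, promoter windows of ±500 bp and ±2.5 kb, coverage of at least 50% of the window, all annotated TSSs, CpG-rich promoters only, circular shifts along the gene order, reciprocal overlap and other stitching distances. CpG-rich promoters had a GC content of at least 50% and an observed to expected CpG ratio of at least 0.6 in TSS ±500 bp. The list test was tested on simulated data over the 21728 genes. With no true difference, 2 of 100 runs gave any call, and of 5 lists simulated at 60% marked promoters against 15% elsewhere, 92% were called. Genes were marked independently of each other in these runs. The rates therefore do not cover domains shared by neighbouring genes, nor lists with a smaller excess. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.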

Results

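H3K27me3 was profiled in the hindbrain of mouse embryos at embryonic day 11.5, when rhombomere identity has been laid down and neurons of many types are being born. A single group of 2 biological replicates was available, so the data answer where the mark lay in this tissue and how far the replicates matched, and nothing was compared with another tissue or stage. The peak list of replicate 1 held 70936 peaks with a median width of 225 bp over 27.9 Mb, and that of replicate 2 held 58995 peaks with a median width of 202 bp over 19.1 Mb. The mean was 64966 ± 8444 peaks and 23.5 ± 6.24 Mb (SD, n = 2). The pooled list held 38772 peaks over 19.4 Mb and the replicated list 26868 peaks over 17.1 Mb, or 0.666% of the genome.

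All 39 Hox genes, which set position along the body axis, had a promoter peak in each replicate, as did all 27 hindbrain neuron subtype factors. Over all 21728 protein-coding genes, 3402 had a promoter peak in both replicates, 1215 in replicate 1 only and 881 in replicate 2 only, where independence would give 910 genes in both (odds ratio 51.6, two-sided Fisher's exact test, p too small to be represented). Genes marked in both carried the stronger promoter peaks, with a median enrichment of 5.09 in replicate 1 and 4.67 in replicate 2, against 3.30 and 3.27 for genes marked in only 1 replicate. Among the genes marked in replicate 1 only, Esrra, which encodes an orphan nuclear receptor, had the peak of highest enrichment (8.47), followed by Galnt16 (6.93) and Rorb (6.60), a nuclear receptor of sensory circuits. Such a split can rest on the edge of the promoter window, since TSS ±5 kb of Esrra was covered over 41.8% in replicate 1 and 34.6% in replicate 2, and its promoter was marked in the replicated list. In replicate 2 only, Tcerg1l (5.74), Krtcap3 (5.38) and Slc26a5 (5.38), the motor protein of outer hair cells, came first.

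At the level of single peaks, 33.1% of the replicate 1 peaks were overlapped by a replicate 2 peak and 50.3% of the replicate 2 peaks by a replicate 1 peak. Circular shifts gave means of 1.45% and 1.83%, and none of the 100 shifts reached the observed share (one-sided permutation p = 0.0099, the smallest possible). The Jaccard index of covered base pairs was 33.4%. Overlapped peaks were stronger and wider. Of the 1000 peaks of highest enrichment, 100% of those in replicate 1 and 99.9% of those in replicate 2 were overlapped, and the median −log10 p in replicate 1 was 6.61 for overlapped peaks and 4.28 for the rest, with median widths of 396 and 199 bp. With a reciprocal overlap of at least 50% required, the mean share of the 1000 strongest peaks overlapped was 58.3% over the 2 replicates. Of the 26868 replicated peaks, 21768 (81.0%) were overlapped in both replicates' own lists, 3972 only in replicate 1, 1110 only in replicate 2 and 18 in neither.

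Replicated peaks were concentrated at promoters. Promoters held 18.4% of the covered base pairs, 11.5 times their share of the genome (1.60%), while exons held 11.4%, introns 33.9% and intergenic sequence 36.3%. In the replicates' own lists the promoter share was lower, 14.6% ± 1.41 (SD, n = 2). A replicated peak lay in the promoter of 3217 genes (14.8%), and in 18.9% of CpG-rich promoters against 11.4% of the others. Coverage of TSS ±5 kb averaged 4.35% over all genes, and 17597 genes (81.0%) had no covered base pair.

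Of the 19 gene lists, 14 passed Fisher's exact test with a higher share of marked promoters than the other genes, none passed with a lower share and 5 did not pass. The neuron subtype factors of the hindbrain, the transcription factors that assign progenitors and newborn neurons to a class, were marked in 27 of 27 cases (Fisher's exact test, adjusted p = 6.92e-22) with a mean coverage of 81.4%, or 77.1% ± 10.5 over the replicates (SD, n = 2). Olig2, which directs motor neuron and oligodendrocyte fate, was covered over 98.7%, and Gata2, a determinant of GABAergic and V2b neurons, over 97.1%. The least covered were Neurog2 (60.1%), a proneural factor, and Ascl1 (24.0%), the proneural factor present in many dividing hindbrain progenitors. Each of the 27 promoters was also marked in each replicate's own list.

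Hindbrain and isthmus patterning factors were marked in 16 of 22 cases (adjusted exact p = 3.74e-09), with a mean coverage of 44.3%, or 44.1% ± 8.18 over the replicates (SD, n = 2). Fgf8, the organiser signal of the isthmus, was covered over 88.0%, Pax2 over 87.9%, Wnt1 over 84.8% and En2 over 79.2%, while Fgf17, also of the isthmus, had 59.3%, Gbx2 47.5% and Pax8 36.4%. Mafb had 73.8% and Egr2 58.3%, both regulators of rhombomere identity. No replicated peak touched TSS ±5 kb of Meis1, Meis2, Pbx1 and Pbx3, which encode the widely present cofactors of Hox proteins, nor of Nr2f1 and Irx5. In the replicates' own lists the first 4 of these also had 0% coverage, while Irx5 had 6.20% ± 1.69 and Nr2f1 0.88% ± 1.24 (SD, n = 2).

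Genes of general neural progenitors were marked in 6 of 16 cases, which passed the test (adjusted exact p = 0.0300), with a mean coverage of 16.9%, and in 8 and 9 of 16 cases in replicates 1 and 2. Pax6, a dorsoventral patterning factor of the neural tube, was covered over 83.5% and Sox1 over 48.7%, whereas Sox2, needed to keep progenitors dividing, was covered over 16.9%, and Nes, Vim and Notch1 had no replicated peak within 5 kb, although Nes and Vim each had a promoter peak in replicate 2 (coverage of 1.55% each). Postmitotic neuron genes were marked in 6 of 16 cases (adjusted exact p = 0.0300) with a mean coverage of 8.77%. Mapt, encoding the microtubule protein tau, was covered over 38.8% and Ina, an intermediate filament of neurons, over 33.1%, while Dcx, Elavl4, Gap43 and Syp were at 0%. With peaks required to cover at least 50% of the promoter window, 6.25% of either list was marked, a share below that of the other genes and without a call, and the postmitotic list passed in replicate 1 but not in replicate 2 (37.5% marked, adjusted exact p = 0.135).

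Mesoderm and limb factors carried a promoter peak in 19 of 22 cases (adjusted exact p = 6.16e-13), with T, the primitive streak factor brachyury, at 96.9% coverage and Pitx1, which specifies the hindlimb, at 95.9%. The myogenic factors Myf5 and Myog and the somite factor Tbx6 were the unmarked members in the replicated list, each at 0%, but Myf5 had a promoter peak in each replicate's own list (coverage of 1.72% and 1.75%), so each replicate marked 20 of 22. Endoderm factors were marked in 11 of 14 cases (adjusted exact p = 3.67e-07). Cdx2, of the hindgut, and Neurog3, of the endocrine pancreas, were covered over 100%, and Hnf1a (11.9%), Foxi1 (0%) and Hnf4a (0%) were unmarked. Among neural crest and mesenchyme markers 11 of 15 were marked (adjusted exact p = 1.07e-06), from Tfap2a (95.1%) to the unmarked matrix genes Col3a1, Dcn and Lum and the pericyte receptor Pdgfrb, all at 0%, although Pdgfrb had a promoter peak in replicate 1. Signalling ligands and antagonists were marked in 20 of 22 cases (adjusted exact p = 2.63e-14). Wnt10a was covered over 96.2%, Wnt10b over 95.7% and Shh, the floor plate morphogen, over 74.2%, while Wnt5a (9.34%) and Fgf4 (2.45%) had no replicated promoter peak but 1 each in replicate 2.

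Endothelial markers were marked in 6 of 12 cases (adjusted exact p = 0.00748), with Flt1, a VEGF receptor, at 72.7%, and with Cdh5, Egfl7, Emcn, Pecam1, Tek and Tie1 unmarked at 0%. Blood cell markers did not pass (3 of 14, adjusted exact p = 0.503), although Tal1, the transcription factor that starts haematopoiesis and also acts in V2b neurons, was covered over 82.6%. Differentiated genes of other organs (1 of 18, adjusted exact p = 0.530), such as Alb and Ins2 at 0%, did not differ from the rest of the genome by the test, and Ckm of muscle (38.9%) was the marked member. Germline and pluripotency genes did not pass either (2 of 15, adjusted exact p = 1), the marked members being Pou5f1 (36.1%) and Nanog (2.80%). Of the housekeeping genes 0 of 20 were marked, with an exact 95% upper limit of 16.8% on their share, which did not pass the test against 14.8% of the other genes (adjusted exact p = 0.0772).

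The genes that encode Polycomb proteins and cell cycle inhibitors did not pass as a list (4 of 15, adjusted exact p = 0.311), but did in replicate 1 (7 of 15, adjusted exact p = 0.0327) and not in replicate 2 (6 of 15, adjusted exact p = 0.128). Its marked members were the cell cycle inhibitors Cdkn2a (87.0%) and Cdkn2b (58.6%) and the chromobox genes Cbx4 (74.4%) and Cbx8 (73.8%), which encode subunits that read the mark. Ezh2, Eed and Suz12, the core of the complex that writes it, were at 0%. Imprinted genes, expressed from a single parental copy, were marked in 6 of 13 cases (adjusted exact p = 0.0111). Dlk1 (69.0%), Grb10 (67.5%), Ascl2 (62.6%), Igf2 (53.3%), Phlda2 (43.1%) and Plagl1 (21.95%) were the marked members, and Mest, Ndn, Nnat, Peg3, Peg10, Slc38a4 and Snrpn were at 0%. Against CpG-rich promoters alone, the imprinted list no longer passed, with 1 of only 4 such members marked (25%, against 18.9% of the others, adjusted exact p = 0.569).

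**Figure D1:**
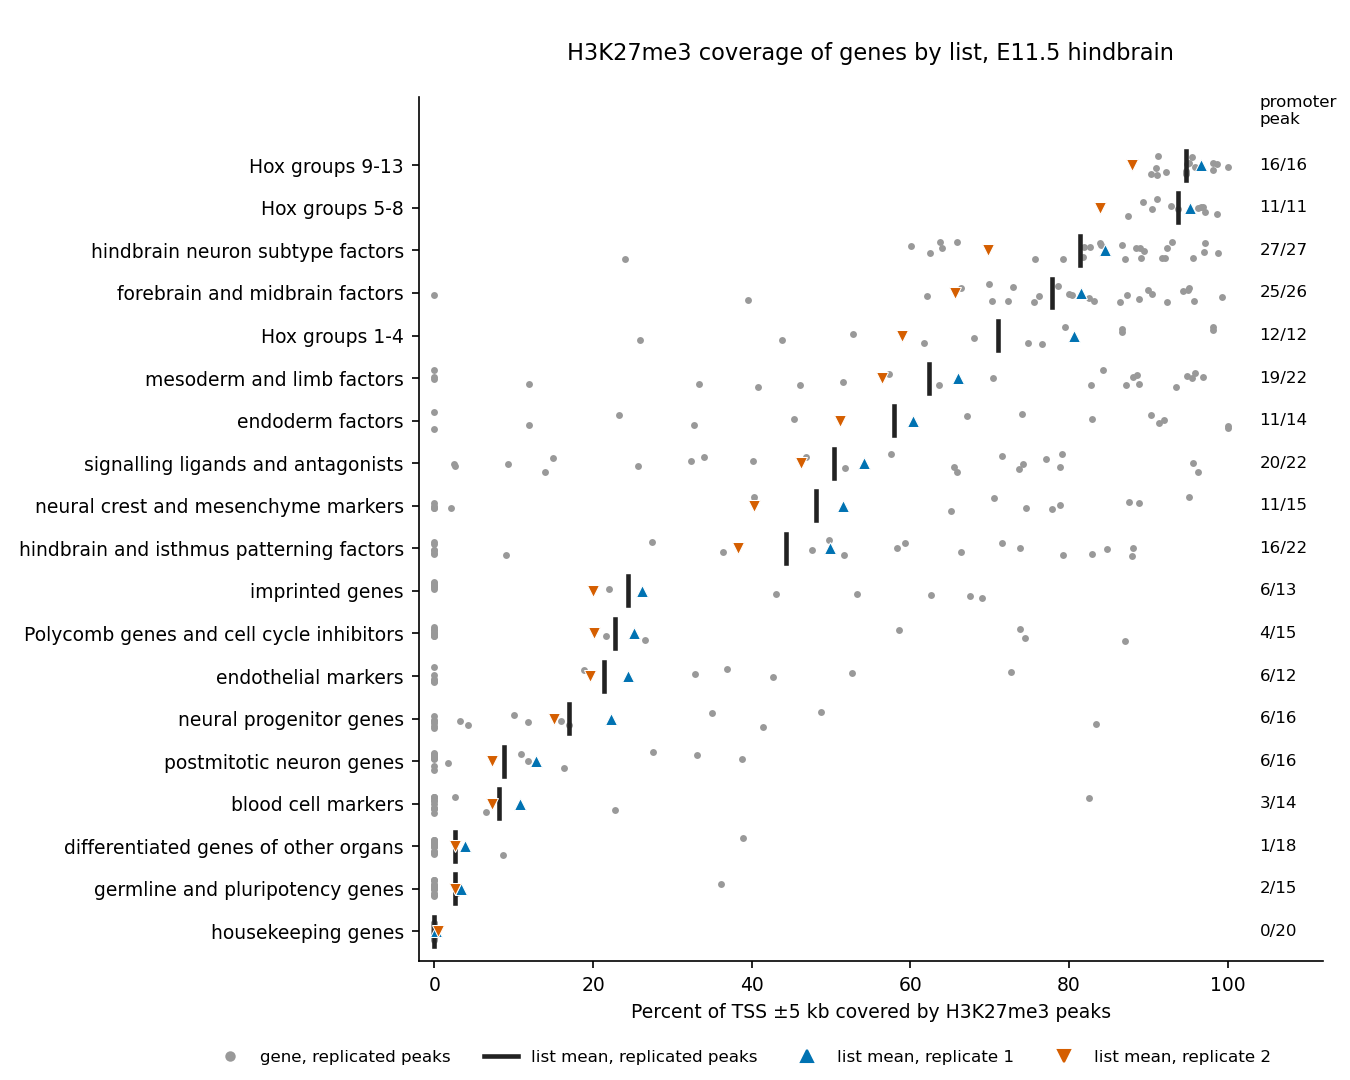
Percent of TSS ±5 kb covered by H3K27me3 peaks (horizontal axis) for the members of the 19 gene lists (vertical axis). Grey points are genes and black bars list means with replicated peaks, triangles are list means with each replicate's own peaks, and the column at the right gives genes with a replicated promoter peak over genes in the list. List means run from 0% for housekeeping genes to 94.8% for Hox groups 9 to 13, and replicate 1 lies above replicate 2 in all lists except the housekeeping genes.

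Hox genes were compared along the cluster because the hindbrain uses paralog groups 1 to 4, while groups 9 to 13 act in the trunk, limbs and tail. All 12 genes of groups 1 to 4 and all 16 of groups 9 to 13 had a promoter peak, but coverage was lower in groups 1 to 4, at 71.1% ± 21.9 (SD over 12 genes), than in groups 9 to 13, at 94.8% ± 2.99 (SD over 16 genes). The difference was −23.7 percentage points (permutation p = 0.0001), and it was −16.05 in replicate 1 (p = 0.00014) and −29.0 in replicate 2 (p = 0.00012). Groups 5 to 8, with 11 of 11 promoters marked, averaged 93.7%. The least covered Hox genes were Hoxa2, the patterning gene of rhombomeres and branchial arch crest (chromosome 6: 52162417–52164831), at 25.9%, Hoxd1 at 43.8%, Hoxa1, an early regulator of hindbrain segmentation, at 52.7%, Hoxb2 at 61.7% and Hoxb1, the identity gene of rhombomere 4, at 68.0%. In the replicates, Hoxa2 had 36.3% ± 16.2 and Hoxb1 66.7% ± 21.7 (SD, n = 2).

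The lowest value among the 16 genes of groups 9 to 13 was that of Hoxd10 (90.4%), and Hoxc12 reached 100%. Within groups 1 to 4, Hoxa3 (98.2%) and Hoxc4 (98.1%) were covered like posterior genes, and Hoxd3 and Hoxd4 followed at 86.6%. The starts of Hoxd3 and Hoxd4 lie at 74711927 and 74711929 on chromosome 2. Their windows are thus nearly identical, yet they count as separate genes in the mean, the SD and the test. The gene records of Hoxa3, Hoxb3, Hoxc4, Hoxd3 and Hoxd4 start far upstream within their clusters, where their longest transcripts begin. Over all annotated starts, Hoxa3 was covered over 92.5%, Hoxc4 over 93.5%, Hoxd3 over 75.0% and Hoxb3 over 78.1%. Hox genes of a cluster share domains, so the permutation p treats as separate what is partly a property of 4 clusters.

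**Figure D2:**
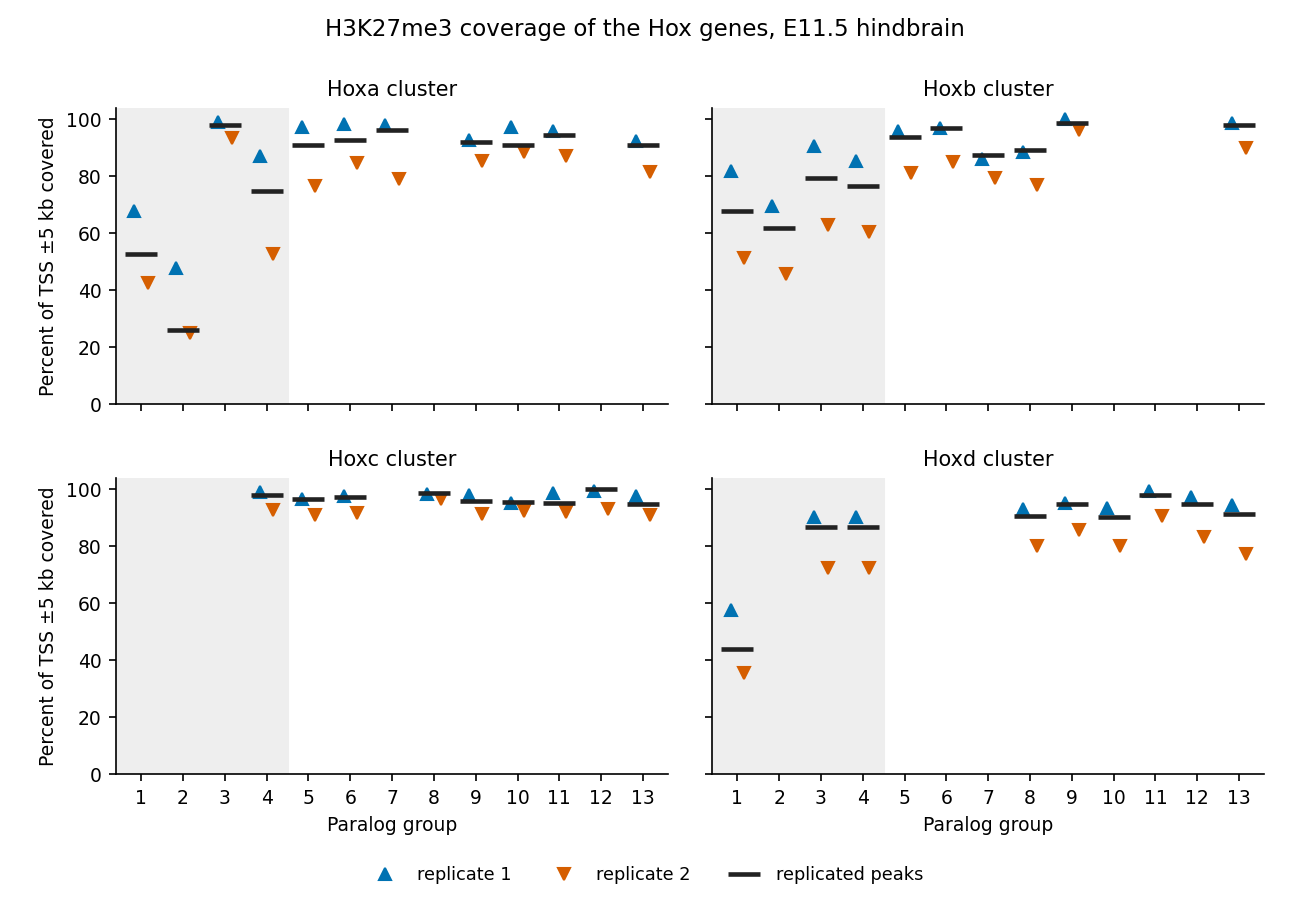
Percent of TSS ±5 kb covered by H3K27me3 peaks (vertical axis) for the 39 Hox genes by paralog group (horizontal axis), with a panel per cluster and groups 1 to 4 shaded. Black bars are replicated peaks and triangles are the peaks of each replicate. Hoxa2 is lowest at 25.9%, and genes of groups 9 to 13 lie between 90.4% and 100%.

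**Figure D3:**
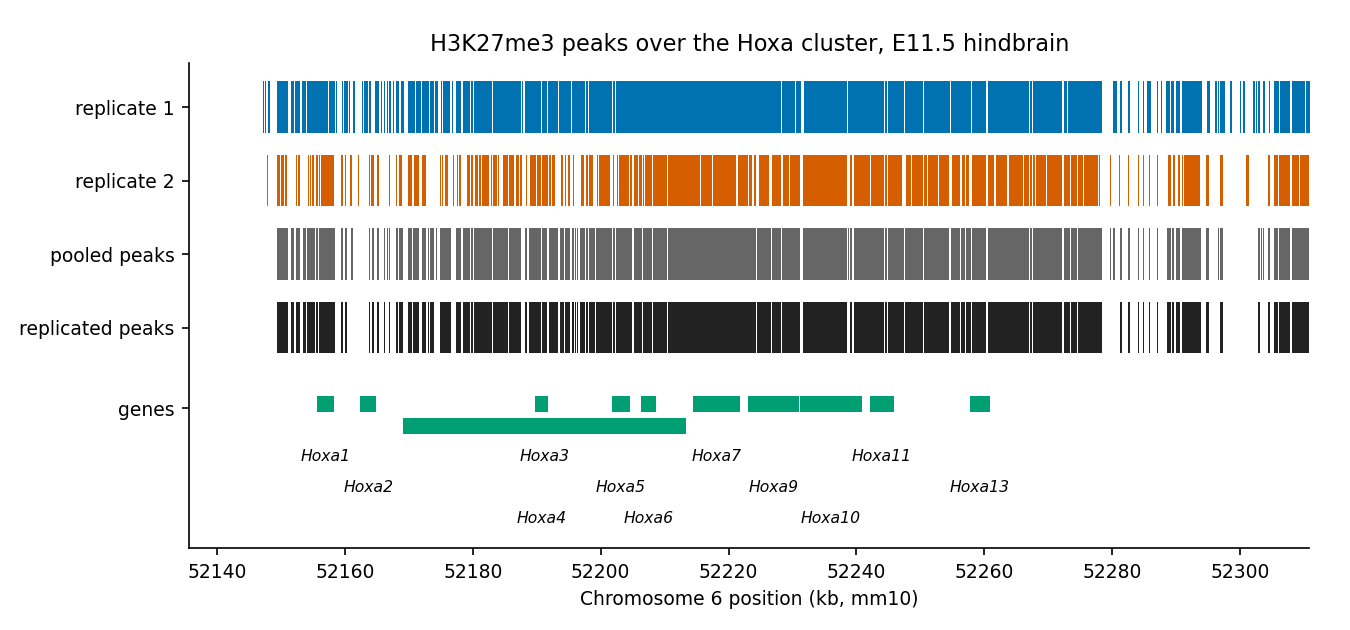
Map of the Hoxa cluster on chromosome 6 (horizontal axis, kb, mm10) with the peaks of the 4 lists as blocks and the records of the Hoxa genes in green. Peaks are sparse between Hoxa1 and the 3′ end of Hoxa3 and nearly continuous from Hoxa5 to Hoxa13.

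Forebrain and midbrain factors were set against both hindbrain lists because the former are known chiefly for roles in front of the hindbrain and the latter for roles in part of its cells. The hindbrain lists also hold the widely present Hox cofactors Meis1, Meis2, Pbx1 and Pbx3. Expression of the genes in these lists was not measured here. Promoter peaks were found at 25 of 26 forebrain and midbrain factors (adjusted exact p = 3.57e-19) and at 43 of 49 hindbrain factors, a difference that did not pass (Fisher's exact p = 0.410) but did when peaks had to cover at least 50% of the window (22.7 points, exact p = 0.0263). Six3, a determinant of the anterior forebrain, was covered over 99.2%, Vax1 over 95.7%, Foxg1, the telencephalic regulator, over 82.6% and Otx2, which sets the midbrain against the hindbrain, over 70.2%. Tbr1 (39.5%) and the unmarked Hesx1 (0%) were lowest. Mean coverage was 77.9% ± 20.6 (SD over 26 genes) against 64.7% ± 31.5 (SD over 49 genes), a difference of 13.2 percentage points that did not pass (permutation p = 0.0527), with 12.6 in replicate 1 (p = 0.0583) and 9.98 in replicate 2 (p = 0.103).

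Each hindbrain list was then compared alone, a choice made after the data were seen. Coverage of the forebrain and midbrain factors was 33.6 percentage points above that of the patterning factors (permutation p = 0.00018), with 31.7 in replicate 1 and 27.3 in replicate 2. Promoter peaks were at 25 of 26 against 16 of 22 (Fisher's exact p = 0.0376), with exact p = 0.0806 in replicate 1 and 0.00608 in replicate 2. No covered base pair was found at 6 of the 22 patterning factors, among them Meis1, Meis2, Pbx1 and Pbx3. The same held for 1 of the 26 forebrain and midbrain factors. These genes enter both differences, and the contrast without them was not run. Against the neuron subtype factors the difference was −3.50 points (permutation p = 0.507). The pooled contrast crossed the threshold under some other settings, for example with peaks of −log10 p of at least 5 (14.5 points, permutation p = 0.0364).

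The Hox clusters held 4 of the 5 longest domains. Stitching gave 8321 domains, of which 209 reached 20 kb and held 28.8% of the covered base pairs. The longest covered 144 kb of the Hoxc cluster (chromosome 15: 102903157–103046886). Those of the other clusters measured 134 kb over Hoxa (chromosome 6: 52163732–52297393, from Hoxa2 to beyond Hoxa13), 112.4 kb over Hoxb (chromosome 11: 96246209–96358576) and 112.1 kb over Hoxd and Evx2 (chromosome 2: 74643374–74755505). Outside them, the longest was a 121 kb domain around Dbx1, a homeobox gene of the p0 interneuron domain (chromosome 7: 49612257–49733246), with 70.5% of its length in peaks. Domains over Nfix (83.8 kb), Rnf220 (75.2 kb), Zic4 and Zic1 (74.9 kb), Neurog1 (69.3 kb), Olig1 (67.6 kb), Tbx3 (65.2 kb), Ap3b1 (58.6 kb), Pax7 (58.6 kb), Tfap2a (52.2 kb) and Pax2 (51.9 kb) completed the 15 longest. The count of domains of at least 20 kb was 383 with replicate 1 and 247 with replicate 2, and each of the 15 was touched by such a domain in both.

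Promoter peaks of the highest enrichment were not at Hox genes alone. Adra2c, encoding an adrenergic receptor (chromosome 5: 35278319–35281763), ranked first at an enrichment of 16.04, followed by Plk5 (15.3), a polo-like kinase of neurons, Klf14 (14.95), an imprinted regulator of fat tissue, Fam43b (14.8) and Hr (14.6), a corepressor of the hair cycle. Olig1 (14.2), Hoxb13 (13.9), Onecut3 (13.5), Insl3 (13.5), a hormone of the testis, and Ptger3 (13.1), a prostaglandin receptor, completed the 10. All 10 promoters had a peak in each replicate, with an enrichment for Adra2c of 16.82 in replicate 1 and 13.998 in replicate 2.

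Chromosome X was compared with the autosomes because the pools mixed males and females and one X is silenced in female cells, where H3K27me3 coats it. The replicates differed here more than on any autosome. Replicate 1 held 10358 peaks on X, or 63.4 per Mb, and ranked it first of the 20 chromosomes at 2.59 times the autosomal median. Replicate 2 held 3585 peaks, or 21.9 per Mb, and ranked it at place 11 with 0.957 times the autosomal median. The ratio of replicate 1 to replicate 2 peaks was 2.89 on X and lay between 1.01 and 1.17 on the 19 autosomes. In the replicated list X had 15.03 peaks per Mb, 1.55 times the autosomal median. By covered base pairs per Mb, X stood at 1.76 times the autosomal median in replicate 1 (place 2), 0.668 times in replicate 2 (place 16) and 0.849 times in the replicated list (place 15), so the replicated list reversed between measures.

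Promoters on X followed the same split. Of 948 genes on X, 238 (25.1%) had a promoter peak in replicate 1, above the 21.1% of autosomal genes (Fisher's exact p = 0.00346), but 161 (17.0%) in replicate 2, below the 19.8% of autosomal genes (Fisher's exact p = 0.0300). With replicated peaks 113 (11.9%) were marked, below 14.9% of autosomal genes (Fisher's exact p = 0.0101). The direction of a difference between X and the autosomes thus depended on the replicate. Of the fixed lists, Arx, a forebrain interneuron factor on X, was covered over 75.5% by replicated peaks and over 64.2% ± 19.2 in the replicates (SD, n = 2), while Sox3 had 3.28% and 9.58% ± 8.07.

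**Figure D4:**
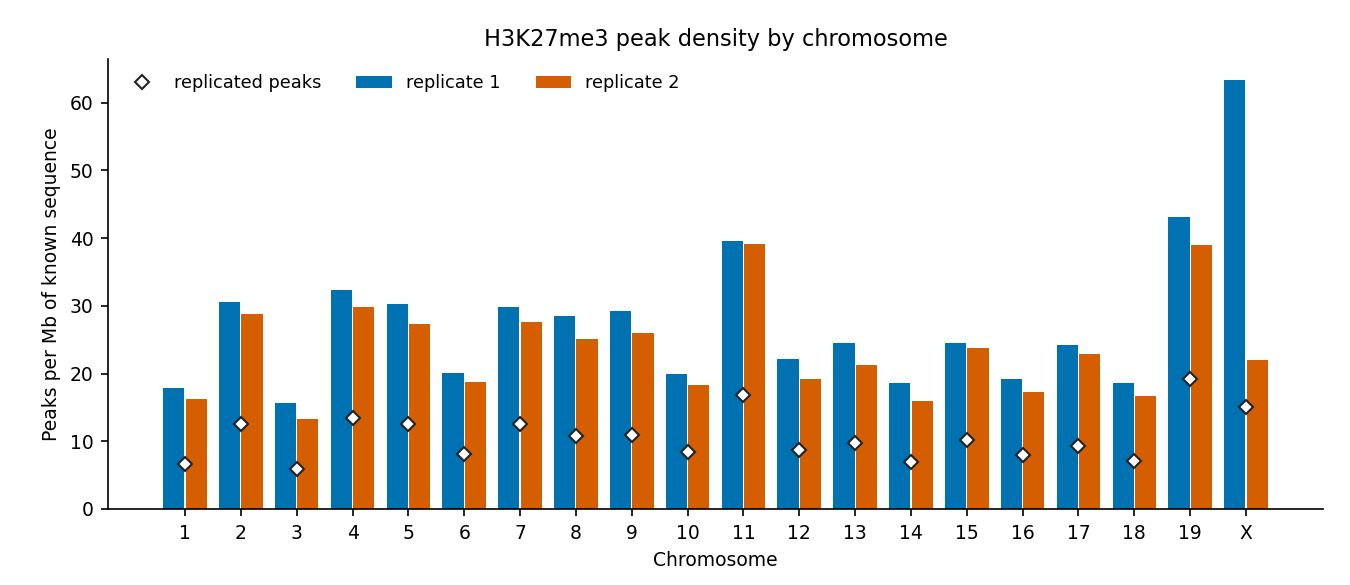
Peaks per Mb of known sequence (vertical axis, from 0) on each chromosome (horizontal axis), with bars for the list of each replicate and diamonds for replicated peaks. On X replicate 1 reaches 63.4 and replicate 2 21.9 peaks per Mb, while the bars of the 19 autosomes differ by a factor of at most 1.17.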

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

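Alternatives chosen after the data were seen were the restriction to autosomes, to replicated peaks overlapped in both replicates' own lists, coverage over all annotated starts, and each hindbrain list alone. Over the 19 lists, 231 comparisons kept direction and call. For the neural progenitor and postmitotic neuron genes, a peak over at least 50% of the promoter window left 6.25% marked, below the other genes and without a call in each. The postmitotic list also lost its call with the 50% of peaks of higher enrichment (25%), with peaks found in both own lists (31.3%) and with any annotated start (37.5%), and ran from 37.5% to 56.3% without single replicates. The housekeeping list, at 0% in each case, passed with pooled peaks, ±2.5 kb and any start. Germline genes reversed with ±500 bp (13.3%) and without replicate 1 (20.0%, and 20.0% without replicate 2), without a call. The Polycomb list passed at 40% with ±2.5 kb and at 46.7% with any start, and passed without replicate 2 (46.7%) but not without replicate 1 (40%). Imprinted genes lost their call among CpG-rich promoters, where 1 of only 4 members was marked (25%). The 14 calls were the same with circular shifts along the gene order. The forebrain contrast in coverage passed with a −log10 p of at least 5 (14.5 points), peaks found in both own lists (13.7), all annotated starts (15.01) and against patterning factors alone (33.6), and reversed against neuron subtype factors alone (−3.50). Its difference in marked promoters passed when 50% of the window had to be covered (22.7 points). The Hox contrast in coverage kept its sign and call under all settings run. In marked promoters, groups 1 to 4 fell to 11 of 12 with a −log10 p of at least 5 and with peaks of higher enrichment. With 50% of the window covered they fell to 10 of 12, while groups 9 to 13 stayed at 16 of 16. None of these differences in marked promoters passed. Peaks per replicate fell to 29481 at a −log10 p of at least 5. The overlap of the strongest peaks was 97.4% for the 5000 strongest and 58.3% with a reciprocal overlap of 50%. Promoters held 15.5% of peaks by summit and 13.7% to 15.6% of base pairs without single replicates. Domains of at least 20 kb numbered 113 when stitched at 1 kb, 413 at 10 kb, and 247 to 383 without single replicates, and 9, 8, 12 and 7 of the 15 longest stayed among the 15 longest at 1 kb, at 10 kb, without replicate 1 and without replicate 2. Coverage of the 146 named genes kept within 1 SD of the replicates in 870 of 1022 comparisons, and 66 genes moved without replicate 1 and 22 without replicate 2. This SD came from the replicates' own values, so it widens where they differ, and the count is no measure of stability. The X density ranged from 0.957 without replicate 1 to 2.59 without replicate 2. Explanations of the X difference were tested among the other observations, and the causes of the other changes were not tested. Sequencing depth is unknown, so its part in these other changes, and in the X difference, could not be fully set apart.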

Other observations

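The tests of gene families, of the rule behind the replicated list and of the Hox clusters were chosen after the results were seen. Genes that fix the transmitter of a neuron were marked in 14 of 20 cases, against 14.8% of the other genes (Fisher's exact test, adjusted p = 9.69e-08 over 23 families), and in 13 and 14 of 20 cases in replicates 1 and 2. Slc6a5, the glycine transporter of inhibitory hindbrain neurons, was covered over 96.4% of TSS ±5 kb, Slc32a1, the vesicular transporter of GABA and glycine, over 91.9%, Gad2, which makes GABA, over 75.5%, and the cholinergic pair Slc18a3 and Chat over 68.9% and 58.1%. Gad1, Th, Tph2, Dbh, Ddc and Hdc had no promoter peak and 0% coverage. Of these 20 genes, 12 are solute carriers, a family of 371 genes with 24.0% marked (adjusted exact p = 5.81e-06). These genes were named after their values were seen.

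Among genes of potassium and calcium channels and their partners, 56 of 94 genes named Kcn (adjusted exact p = 1.46e-22) and 14 of 26 named Cacn (adjusted exact p = 7.49e-06) were marked, and of the Kcn genes with a CpG-rich promoter 31 of 35 were marked against 18.7% of other such genes. Kcnh3 (77.7%), Kcnc4 (63.9%) and Kcnj4 (61.9%) were the most covered, chosen after their values were seen. Families of transcription factors and ligands were marked at 12 of 12 LIM homeobox, 13 of 14 Nkx, 8 of 9 Pax, 17 of 19 Wnt, 27 of 44 Fox and 11 of 19 Sox genes. Lower shares than elsewhere were found for zinc finger genes named Zfp (17 of 394, adjusted exact p = 8.36e-11), ribosomal protein genes (2 of 91, adjusted exact p = 0.000188), clustered histone genes (0 of 67, adjusted exact p = 5.46e-05), genes named Nduf (1 of 46, adjusted exact p = 0.0132), olfactory receptors (0 of 1134, adjusted exact p = 2.04e-80) and vomeronasal receptors (0 of 330, adjusted exact p = 1.23e-22). Neighbouring genes are not independent units in these exact tests. With circular shifts along the gene order, the adjusted p was 0.0346 for histone, 0.0239 for Nduf and 0.00311 for ribosomal protein genes. It was 0.000153 each for Zfp genes, olfactory receptors and vomeronasal receptors. Olfactory receptor promoters had no CpG-rich member and vomeronasal receptor promoters only 1 of 330, so CpG content cannot be held equal there. In all, 13 of 23 families were higher, 6 were lower and 4 did not pass.

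The excess of X peaks in replicate 1 is the pattern that most asks for follow-up. Greater depth or a looser threshold in replicate 1, acting alike on all chromosomes, is argued against as the whole cause. Peaks with a −log10 p under 5 were 2.46 times as many on X but at most 1.16 times on any autosome. Stronger peaks were 3.599 times as many on X and at most 1.215 times on any autosome. Yet replicate 1 covered 1.271 to 1.497 times the base pairs of replicate 2 on the autosomes, against 3.508 times on X. Depth is unknown, and these ratios cannot exclude it if X held more signal near the threshold than the autosomes. An even shift of all X sequence failed the bound set in advance, a share of summits in gene bodies near that of the sequence. Of the summits of the 8508 X peaks that replicate 2 lacks, 51.0% lay in gene bodies, which make up 27.5% of X. That bound was wrong, since a shift lifting signal already there would give the 51.6% found for all X peaks of replicate 2. The latter comparison was not among the bounds set in advance, so an even shift stays open. The 10 fullest of the 172 bins of 1 Mb on X, or 5.81% of the bins, held 41.7% of these peaks. At least 1 of the peaks lay in 96 of the bins. The share of 41.7% lay between the bounds set for a few loci and for a broad spread, so the few-loci explanation stays open. A different share of female embryos in the pools could give such an excess through the inactive X, but the labels give no sex ratio, and random pools of 109 and 88 embryos would differ by 7.17 percentage points (1 SD) in female share, so this remains untested.

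Of the replicated peaks, 14.9% had no overlapping peak in the list of replicate 2. If the replicated list held only peaks overlapped in both deposited lists, none should lack an overlap, but 18.98% lacked one in at least 1 list, which argues against that rule. The X surplus of replicate 1 does not account for it either, since 13.4% of autosomal replicated peaks lacked a replicate 2 peak, against 29.4% on X. The deposited descriptions name only the replicates' lists and the pooled list as its sources, and which rule was applied to them stays open. No biological explanation was tested.

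The lower coverage of Hox groups 1 to 4 was weighed against their place at the cluster end. With each window clipped to the span of its cluster's gene records, groups 1 to 4 were still covered by −22.8 percentage points relative to groups 9 to 13 (permutation p = 0.0002), and by −15.4 and −27.4 points in replicates 1 and 2, which argues against windows that reach outside the cluster as the whole cause. Across all 39 genes, which are not independent replicates, coverage rose with paralog group (Spearman's rho = 0.523, permutation p = 0.00072; Pearson r = 0.629, and 0.606 without the 2 genes farthest from the median group). Within groups 5 to 13 rho was 0.0587 (permutation p = 0.771), so the relation rested on groups 1 to 4. Inside these, genes of groups 1 and 2 were covered over 25.9% to 68.0% and those of groups 3 and 4 over 74.9% to 98.2%. Over all annotated starts the values of groups 1 and 2 also stayed below those of groups 3 and 4. This split was seen after the values were known. The records of Hoxa3, Hoxb3, Hoxc4, Hoxd3 and Hoxd4 start far upstream, and the means over all starts include those starts. Hoxa4 (74.9%) and Hoxb4 (76.6%), with 1 annotated start each, lay above groups 1 and 2 but below the 93.7% mean of groups 5 to 8. The split therefore cannot decide on a single step between groups 4 and 5. That step, a step at a lower group and a graded relation cannot be told apart. A candidate explanation is that cells expressing groups 1 to 4 lack the mark there, which would need expression data to test.

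On chromosome 17, the region 39843076–39848885 held peaks with an enrichment of 2.45 and 2.43 in the replicated list, at percentiles 2.99 and 2.74 of that list, that ranked at places 3 and 4 of all 26868 by −log10 p (48.6 and 47.2). Both replicates had peaks there, with enrichments between 2.28 and 2.64. No peaks were removed here for lying in repeated sequence. Why a low enrichment went with a high −log10 p in this region was not tested. The pooled list held fewer peaks (38772) than the list of either replicate.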
